A study of Mus musculus with 6 samples.

How the data were processed

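The deposited table holds log2 expression values of 28853 probe sets on 6 Affymetrix mouse arrays, 3 of Ly-6C-positive and 3 of Ly-6C-negative naive CD4 T cells. Per the labels' protocols, the cells were enriched with magnetic beads and sorted, total RNA was extracted with a column kit, 50 ng of it was amplified by whole-transcriptome amplification and 5 µg of the cDNA was labelled with biotin. Per the submitters' processing notes, RMA and Partek were used, with neither version nor role stated. RMA corrects background, makes the arrays' distributions alike by quantile normalization and summarises each probe set on the log2 scale, so a change of total RNA shared by all genes cannot be seen and differences of dim genes are compressed near background. The deposited log2 values ran from 2.47 to 13.6 with near-equal quartiles on all arrays, as RMA gives. They were used as deposited. The version of the chip description and the genome build are not given in the sources used here, and no coordinates are printed. The labels call the arrays biological replicates without saying which mice gave which cells.

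Probe sets were named through the platform annotation: 21789 had 1 gene symbol, 1621 had several and 5443 were not listed. Of those with 1 symbol, 21698 were matched to a current gene by Entrez ID. Probe sets with several symbols or none were left out of the gene table. Where a gene had more than 1 probe set, as 999 genes did, the probe set with the highest mean over the 6 arrays was used, which left 19938 genes. The groups, tests, gene lists, named-gene rule and alternatives were fixed before the data were examined. The fixed lists hold 765 distinct genes, of which 91 were not analysed here, 40 of them because their probe sets carry several symbols.

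Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided), on all genes without a filter on dim genes, with Benjamini-Hochberg adjustment over all genes tested and a threshold of adjusted p 0.05. The fit had no covariate. The limma model adds 5.56 prior degrees of freedom to those of the arrays. Each gene list with at least 3 measured members was tested with limma's camera with a preset correlation of 0.01 between genes, and adjusted over the 31 lists. The camera test compares a list with the other genes. Members were also counted after adjustment over the list alone. A list of T cell receptor segments, taken by symbol, was added to the 30 lists written by gene. Median, mean and camera direction differed in sign for the lists of T cell receptor signalling machinery, apoptosis regulators, dissociation and stress genes, B cell markers, NK and innate lymphoid markers and sex-linked genes, none of which passed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

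The genes named are the up to 12 genes with the largest difference in each direction among those past the threshold whose groups do not overlap, leaving out predicted models, small RNAs and receptor segments; up to 4 members per list with the smallest p; the gate genes; and a short fixed set that includes Cd5, Cd6, Nr4a1, Tgfbr2, Ccr7, Il7r, Dntt and Eomes. Not every gene the rule names is printed. Some items of the rule are not reported here. Genes named outside the rule are the markers used in the tests of cell shares and those said to be named after their values were seen.

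Replicate numbers are shared by both groups. The deviations of same-numbered arrays from their group means correlated across genes with r of 0.129, 0.128 and 0.107 for replicates 1, 2 and 3, and the highest r between different numbers was -0.011. Centring on group means pushes values between different numbers down whenever same-numbered ones are positive, so the former are no separate evidence of pairing. All 3 lie above 0.1, the bound set for reading the numbers as pairs, although replicate 3 reached 0.0856 when every probe set was used. The pairing is read from these values and not stated by the labels. The fit with the replicate number as a block was an alternative, and called 41 genes, 28 higher and 13 lower in Ly-6C-negative cells, 27 of them among the 29 called without it.

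The other alternatives were a second quantile normalization, subtraction of array medians, leaving out genes dimmer than the median gene, every probe set as its own feature, the mean of a gene's probe sets, eBayes with trend and robust settings, array weights, leaving out each array in turn, an adjusted p of 0.1, a 1.5-fold minimum, and leaving out the Ly6 family. For the lists, an estimated correlation, limma's fry and leaving out shared members were tried. The steps were tested on simulated data of 19938 genes in 20 runs with 200 changed genes: 65.7% of changes of 0.5 on the log2 scale were recovered, 95.9% of changes of 1 and 99.0% of changes of 1.5, all in the right direction, and 4.62% of calls were false. A list of 37 genes shifted by 0.15 was called in all 20 runs. The simulated genes were drawn independently of each other and without replicate pairs. These rates therefore do not cover correlated genes or paired arrays. The SDs were the real ones shuffled between genes. With 200 changed genes the adjustment over all genes is also milder than with the 29 genes called in the real data. Recovery there, above all of changes of 0.5, may therefore be lower.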

Results

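Gene expression was measured in naive CD4 T cells that carried or lacked Ly-6C, a surface protein of the Ly6 family anchored in the membrane by a lipid. The cells came from peripheral lymph nodes of C57BL/6 Foxp3-GFP mice aged 6 weeks, in which a fluorescent protein reports Foxp3, the transcription factor of regulatory T cells. Both populations were sorted as CD4+, CD8-negative, TCRβ+, CD44-low, CD25-negative and Foxp3-negative, and then by Ly-6C. Each population was hybridised on 3 Affymetrix arrays, labelled as biological replicates, which makes 6 arrays and 28853 probe sets. The median log2 expression of an array lay between 6.25 and 6.29, and the number of arrays limits the precision of every value. Arrays of the same group correlated with r from 0.993 to 0.998 across genes, and arrays of different groups with r from 0.994 to 0.997. The first principal component held 34.6% of the variance and set Ly-6C-negative replicate 2, with a score of 19.9, apart from Ly-6C-negative replicate 3, with a score of -10.0. The comparison asks which transcripts differ between naive CD4 T cells without and with Ly-6C, and every difference is Ly-6C-negative minus Ly-6C-positive.

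Transcripts of Ly-6C itself followed the sort. A pair of probe sets is listed under both Ly6c1 and Ly6c2, near-identical copies that these probe sets do not separate. Probe set 10429568 measured 11.66 ± 0.067 (SD, n = 3) on the log2 scale in Ly-6C-positive cells and 8.49 ± 0.24 (SD, n = 3) in Ly-6C-negative cells, 9.03-fold lower (limma adjusted p = 3.94e-05 over all probe sets). Probe set 10429573 was 6.03-fold lower in Ly-6C-negative cells (limma adjusted p = 0.000675). The other genes of the gate did not pass the test: the differences were -0.089 for Cd4, 0.013 for Foxp3, 0.12 for Il2ra, which encodes CD25, -0.029 for Cd8a and -0.12 for Cd8b1. Cd44 differed by -0.25 with a standard error of 0.066 (limma adjusted p = 0.427), with all Ly-6C-negative arrays below all Ly-6C-positive arrays. As a list of 6 measured genes, the gate genes had 0 members past the threshold over all genes and 1, Cd44, adjusted over the list alone (camera adjusted p = 0.362).

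**Figure D1:**
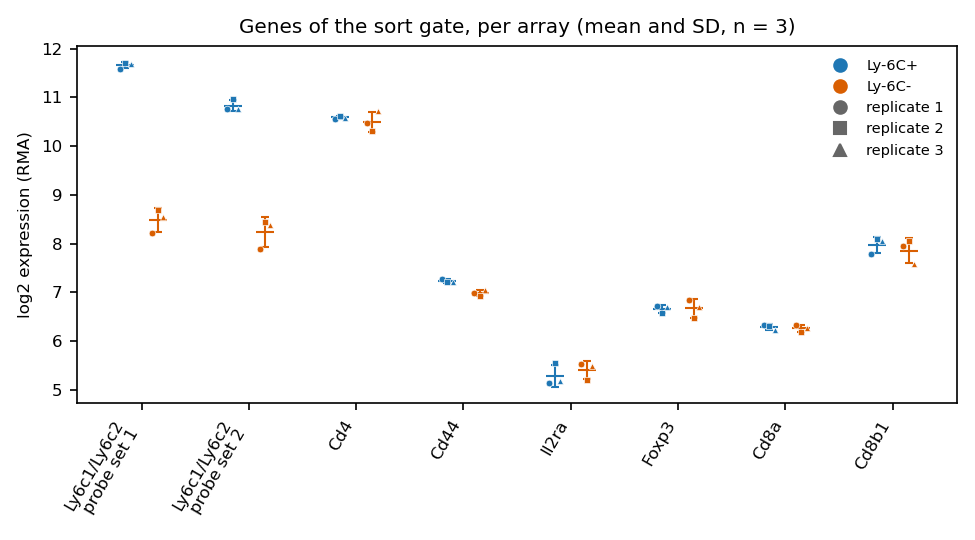
Log2 expression (RMA) of the gate genes in each array, with points for replicates and bars for the group mean and SD (n = 3). Both probe sets listed under Ly6c1 and Ly6c2 were lower in all 3 Ly-6C-negative arrays, with means of 8.49 against 11.66 and 8.24 against 10.83; Foxp3 had means of 6.67 and 6.66.

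Ly-6C-negative cells had more transcript of Ctla4, an inhibitory receptor of T cells, of Il2rb, the beta chain of the receptors for IL-2 and IL-15, and of Izumo1r, also known as folate receptor 4. Ctla4 (probe set 10346790) measured 9.76 ± 0.19 (SD, n = 3) against 8.43 ± 0.31 (SD, n = 3), a difference of 1.34 or 2.53-fold (limma adjusted p = 0.0121). Il2rb was higher by 1.12 or 2.18-fold (limma adjusted p = 0.000860) and Izumo1r by 1.03 or 2.04-fold (limma adjusted p = 0.00200). Cd200, whose product engages an inhibitory receptor, was higher by 0.86, the chemokine receptor gene Ccr8 by 0.65 and Ikzf2, which encodes the transcription factor Helios, by 0.63. In all, 29 of 19938 genes passed the limma threshold of adjusted p 0.05, 20 of them higher and 9 lower in Ly-6C-negative cells.

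The other genes named among those higher in Ly-6C-negative cells were Itih5 at 1.03, Marcks, a protein kinase C substrate, at 0.87, the Rac regulator Chn2 at 0.81, the epoxide hydrolase gene Ephx1 at 0.73, Phactr2 at 0.72 and the claudin gene Cldn10 at 0.66. Tnfrsf9, which encodes the costimulatory receptor 4-1BB, was higher by 0.50. The limma adjusted p of these 7 genes and of Cd200, Ccr8 and Ikzf2 lay between 0.000860, for Itih5, and 0.0325, for Tnfrsf9. Of the 7 remaining genes, 3 are predicted models and 4, named after their values were seen, are Gpr83 at 0.56, Sypl at 0.50, Nod1 at 0.43 and Zfp101 at 0.43. With the replicate number as a block, Nod1 (limma adjusted p = 0.0739) and Zfp101 (limma adjusted p = 0.0795) no longer passed.

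Ly-6C-negative cells had less transcript of Klrd1, the gene of the NK receptor chain CD94, and of Dntt, the gene of terminal deoxynucleotidyl transferase, which adds nucleotides to receptor gene joints in the thymus. Klrd1 (probe set 10542214) measured 7.03 ± 0.41 (SD, n = 3) against 8.53 ± 0.26 (SD, n = 3), a difference of -1.50 or 2.83-fold lower (limma adjusted p = 0.0263). Dntt measured 5.66 ± 0.31 (SD, n = 3) against 7.04 ± 0.15 (SD, n = 3), a difference of -1.37 or 2.59-fold lower (limma adjusted p = 0.00768). The nucleoside transporter gene Slc28a2b was 2.01-fold lower (limma adjusted p = 0.00200), and the granzyme gene Gzma and the IL-18 receptor gene Il18r1 differed by -0.69 and -0.67 (limma adjusted p of 0.0392 and 0.0325). Adam6b, the aldo-keto reductase genes Akr1c13 and Akr1c12, and the monocarboxylate transporter gene Slc16a5 differed by -0.63, -0.60, -0.56 and -0.60, with limma adjusted p of 0.0240, 0.0263, 0.0392 and 0.0263. In each of the 29 genes the arrays of the groups did not overlap, as in 2516 of all genes, or 12.6%, where chance gives 10%. Leaving out Ly-6C-positive replicate 1, 2 or 3 gave 8, 6 or 8 genes, and leaving out Ly-6C-negative replicate 1 or 2 gave 5 or 47. All 29 genes kept their direction each time, which follows from their groups not overlapping and is no separate support. With an array left out, Klrd1 lost its call in 5 fits (limma adjusted p up to 0.199). Ctla4 and Dntt lost theirs in 3 each (limma adjusted p up to 0.140 and 0.0915). Il2rb, Izumo1r and Slc28a2b passed under every alternative run, as did Itih5 except that it was not tested without dim genes.

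**Figure D2:**
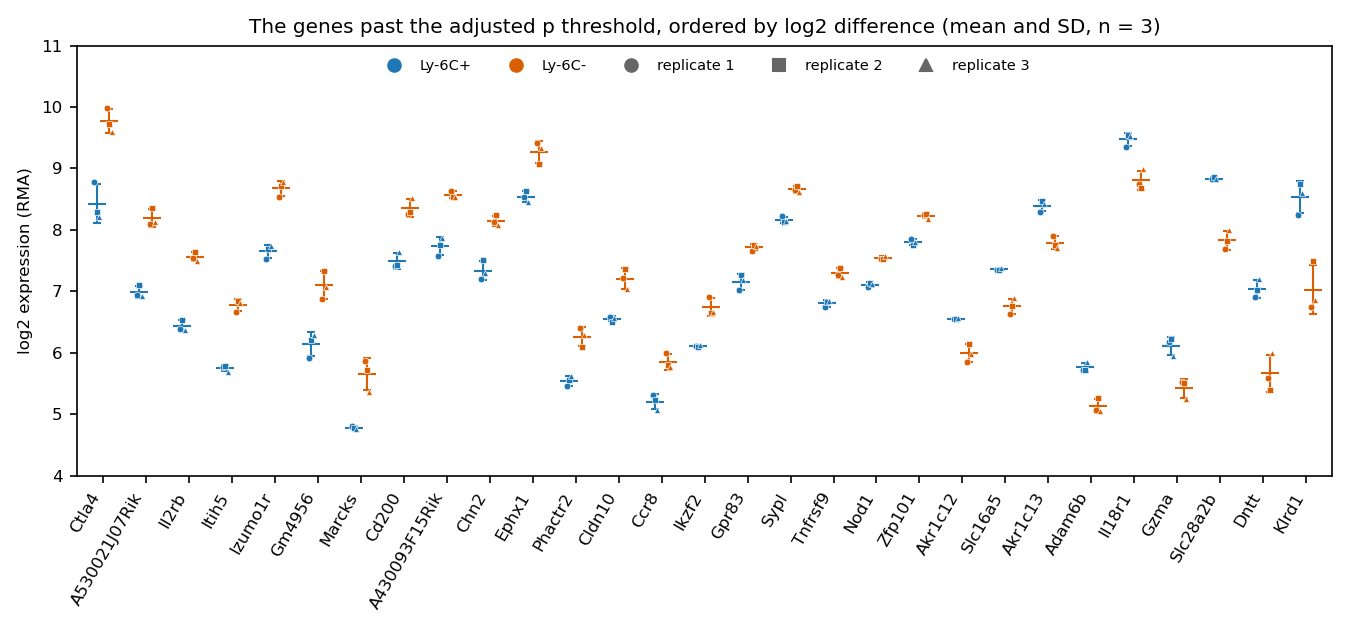
Log2 expression (RMA) of the 29 genes past the threshold in each array, with points for replicates and bars for the group mean and SD (n = 3). From left to right the difference goes from 1.34 for Ctla4 to -1.50 for Klrd1, and in each gene the points of the groups do not overlap.

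Genes of the regulatory T cell signature were higher in Ly-6C-negative cells, while Foxp3 did not pass the test. Of 38 measured members, 6 passed over all genes and all were higher: Ctla4, Il2rb, Izumo1r, Ikzf2, Gpr83 and Tnfrsf9. Adjusted over the list alone, 18 were higher and 1 lower, the lower one being Dapl1 at -0.49, which is also in the naive and quiescence list. The list does not separate genes that regulatory T cells raise from genes that they lower. A lower member therefore need not go against the signature, nor a higher one with it. The list's median difference was 0.16, with 31 members above 0 (camera adjusted p = 2.05e-16). Icos, a costimulatory receptor gene, differed by 0.64 and Tnfrsf1b, a TNF receptor gene, by 0.52; with the replicate number as a block they passed at limma adjusted p = 0.0204 and 0.0295, and without it they did not, at 0.145 and 0.426. Nt5e, named after its values were seen, differed by 0.73 and likewise passed with the block only, at 0.00602 against 0.427, which made 9 members past the threshold instead of 6. Over all alternatives the limma adjusted p ran from 0.00526 to 0.619 for Icos, the lowest without Ly-6C-negative replicate 2, and from 0.0295 to 0.885 for Tnfrsf1b; Dapl1, not past the threshold at 0.477, passed without that array at 0.0250 in a range up to 0.981.

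As lists, genes induced early by T cell receptor signals and genes of inhibitory receptors and anergy were also higher in Ly-6C-negative cells. Of 31 measured early genes, 3 passed over all genes, Izumo1r, Cd200 and Tnfrsf9, and 13 were higher adjusted over the list alone. With the replicate number as a block 5 passed over all genes, adding Icos and Ubash3b, the latter named after its values were seen, at 0.65 (limma adjusted p = 0.0115 with the block and 0.312 without). Among these 13 were Cd5, a receptor whose level follows the strength of T cell receptor signals, at 0.41 with a standard error of 0.076, Cd6 at 0.43 with a standard error of 0.079, and Nr4a1, the gene of Nur77, at 0.34 with a standard error of 0.074. Over all genes none of these 3 passed, with limma adjusted p of 0.139, 0.139 and 0.256; Cd5 and Cd6 passed without Ly-6C-negative replicate 2, at 0.0341 and 0.0437, in ranges over the alternatives of 0.0311 to 0.581 and 0.0370 to 0.619. The early list had a median difference of 0.16 with 24 members above 0 (camera adjusted p = 1.67e-13). The other 7 lay below 0, Cd40lg at -0.18 among them. Nr4a2, Dusp2 and Egr1, named after their values were seen, differed by 0.23, 0.19 and 0.11 and did not pass adjusted over the list alone. Of 27 measured inhibitory and anergy genes, 3 passed over all genes, Ctla4, Izumo1r and Cd200, and 7 were higher adjusted over the list alone, Tnfrsf4 at 0.39 among them; with the block 4 passed over all genes, Nt5e being added. Their median difference was 0.081, with 23 members above 0 (camera adjusted p = 8.47e-11). The lists share members: Izumo1r belongs to all 3, and 8 inhibitory and anergy genes are in the regulatory T cell list. These 3 lists were the ones that passed with an estimated correlation, at camera adjusted p = 0.0423 for the regulatory T cell list, 0.0375 for the early list and 0.0423 for the inhibitory list.

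Thymocyte genes moved both ways. Of 31 measured members of the thymocyte and recent thymic emigrant list, Ctla4 and Cldn10 were higher and Dntt and Slc16a5 lower over all genes, and 6 were higher and 2 lower adjusted over the list alone. The replicate block added Cd24a, named after its values were seen, which made 5 past the threshold over all genes, 3 higher and 2 lower. The median difference was 0.077 with 22 members above 0 (camera adjusted p = 0.000245; adjusted p = 0.0729 with an estimated correlation). Cell cycle genes had a median difference of 0.045 with 27 of 39 members above 0 (camera adjusted p = 0.000222; adjusted p = 0.112 with an estimated correlation). None of them passed over all genes and 1, the topoisomerase gene Top2a at 0.49, passed adjusted over the list alone; Mki67 differed by 0.36, Cdc6 by 0.35 and Stmn1 by 0.29. Over all genes Top2a passed without Ly-6C-negative replicate 2 (limma adjusted p = 0.0385), in a range over the alternatives of 0.0220 to 0.619. The TGF-beta pathway list had a median difference of 0.064 with 25 of 35 members above 0 (camera adjusted p = 0.00201; adjusted p = 0.0916 with an estimated correlation). None of its members passed over all genes, and adjusted over the list alone 1 was higher, Id2 at 0.58, and 1 lower, Bmpr1a at -0.35. Id2, a transcriptional inhibitor, passed over all genes with the replicate number as a block (limma adjusted p = 0.0158) and not without it (limma adjusted p = 0.144), in a range up to 0.590. The receptor gene Tgfbr2 differed by 0.068.

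Effector and memory genes were split. Of 52 measured members, Il2rb was higher and Klrd1, Il18r1 and Gzma were lower over all genes, and 8 were higher and 4 lower adjusted over the list alone, with Eomes, a T-box factor gene, at 0.27. The replicate block added Id2, which made 5 past the threshold over all genes, 2 higher and 3 lower. The median difference was 0.049 (camera adjusted p = 0.00827; adjusted p = 0.531 with an estimated correlation), and the call was lost under 4 of 17 alternatives, among them without Ly-6C-negative replicate 2 (camera adjusted p = 0.205). Of 36 cytokine receptor and JAK-STAT genes, Il2rb was higher and Il18r1 lower both over all genes and adjusted over the list alone, with Stat5b at 0.21 and Il15ra at -0.24. Their median difference was 0.042 (camera adjusted p = 0.0438; adjusted p = 0.531 with an estimated correlation; adjusted p = 0.0527 with the replicate number as a block), and the call was lost under 10 of 17 alternatives, among them without Ly-6C-positive replicate 1 (0.161) or Ly-6C-negative replicate 3 (0.782). The Ly6 family list, which held neither Ly6c1 nor Ly6c2 because their probe sets are shared, had a median difference of -0.039 over 19 members (camera adjusted p = 0.0436; adjusted p = 0.247 with an estimated correlation; adjusted p = 0.0714 with the block), and the call was lost under 9 of 17 alternatives, with adjusted p up to 0.366, among them without Ly-6C-positive replicate 1 (0.216), Ly-6C-negative replicate 1 (0.0830) or Ly-6C-negative replicate 2 (0.228). None of its members passed over all genes or adjusted over the list alone; Ly6e differed by -0.34, Lypd3 by -0.25, Ly6g6d by -0.22 and Lynx1 by -0.18. In all 9 of 31 lists passed, 8 higher and 1 lower, and 1 of the 9 other groupings of the arrays into 3 and 3 gave 7 lists.

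**Figure D3:**
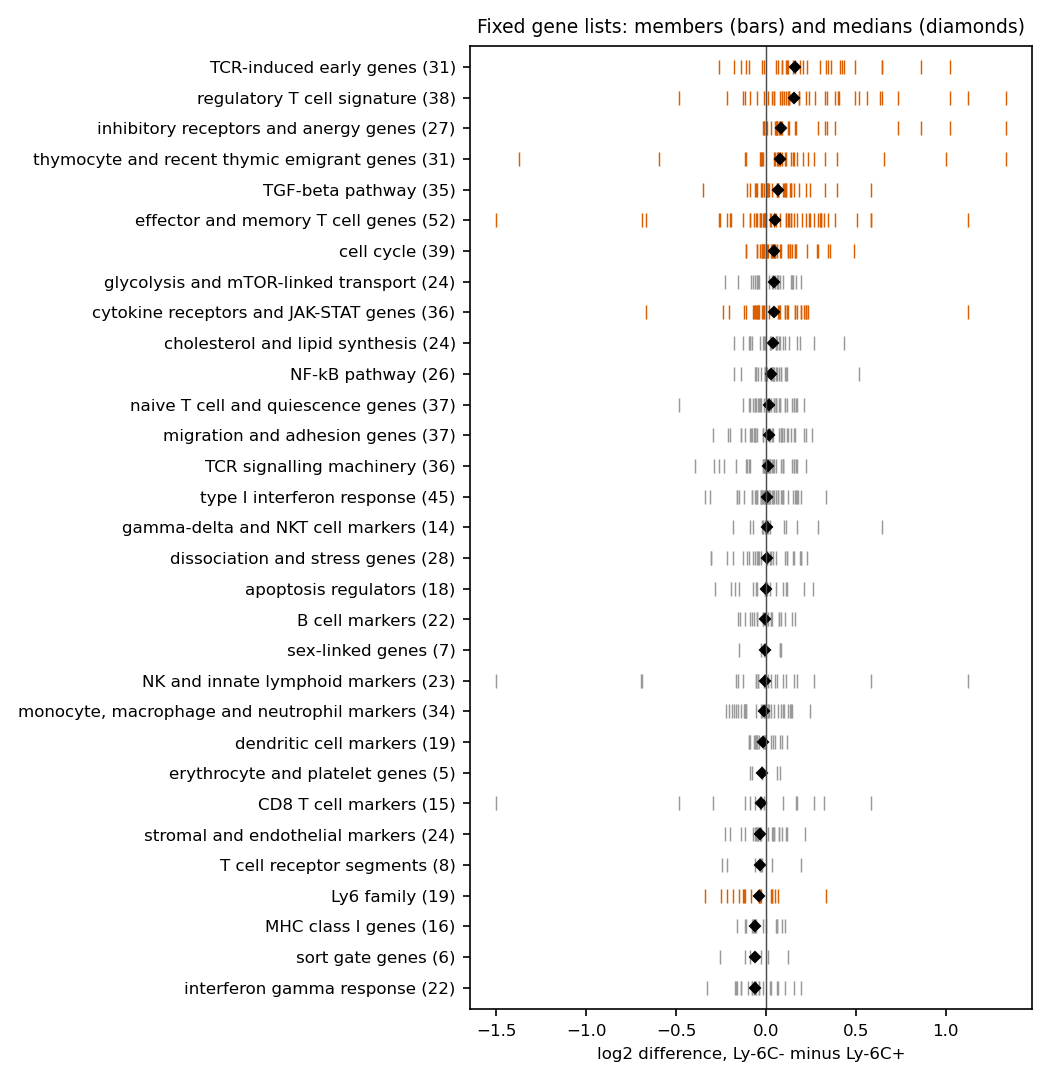
Log2 difference, Ly-6C-negative minus Ly-6C-positive, of each member (bars) and the median (diamonds) of the 31 lists, with the number of measured members in parentheses and orange bars for the 9 lists past the camera threshold. The medians go from 0.16 for the early T cell receptor genes to -0.060 for the interferon gamma list.

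Marker lists of other cell types did not pass the threshold. The NK and innate lymphoid list had a median difference of -0.0077 over 23 members (camera adjusted p = 0.923), with Il2rb higher and Klrd1 and Gzma lower over all genes and 3 higher and 3 lower adjusted over the list alone. With the replicate number as a block 5 of its members passed over all genes, adding Id2 and Prf1, the perforin gene, named after its values were seen, at -0.70 (limma adjusted p = 0.00848 with the block and 0.145 without). The CD8 T cell list had a median difference of -0.029 over 15 members (camera adjusted p = 0.949), with Klrd1 lower over all genes, 3 higher and 3 lower adjusted over the list alone, and Crtam at -0.29. B cell markers had a median difference of -0.0031 over 22 members (camera adjusted p = 0.949), with Cd74 at 0.16, and monocyte, macrophage and neutrophil markers -0.0093 over 34 members (camera adjusted p = 0.518), with Fcer1g at -0.17 and Lyz2 at 0.25. Dendritic cell markers had a median difference of -0.015 over 19 members (camera adjusted p = 0.885), stromal and endothelial markers -0.031 over 24 members (camera adjusted p = 0.923), and erythrocyte and platelet genes -0.021 over 5 members (camera adjusted p = 0.949). In these 5 lists no member passed over all genes or adjusted over the list alone. Markers of gamma-delta and NKT cells had a median difference of 0.0058 over 14 members (camera adjusted p = 0.237), with 0 members past the threshold over all genes and 1, Icos, adjusted over the list alone and, with the block, over all genes; without dim genes this list passed (camera adjusted p = 0.00539), in a range over the alternatives up to 0.667. The sex-linked list had a median difference of -0.0046 over 7 members (camera adjusted p = 0.923), with Xist at -0.15 and Eif2s3y at 0.079 and no member past either threshold.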

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

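The test over every probe set was planned, and no test in this part was chosen after the result was seen. Outside the table of named genes, 7064 probe sets have several symbols or are not listed in the annotation. Among all 28853 probe sets, 17 of these were higher in Ly-6C-negative cells and 3 were lower past a limma adjusted p of 0.05, a signal in data that the comparison by gene does not use. The 17 were higher by 0.48 to 0.82 on the log2 scale. Among them 2 carry several symbols, 15 are not listed, and 2 hold identical values. Their median pairwise correlation across the 6 arrays was 0.990, so they may not be 17 separate transcripts, although a shared group difference also raises it. Of the 3 lower ones, 2 are the probe sets listed under both Ly6c1 and Ly6c2, and 1 is not listed. No explanation was tested for the unnamed probe sets.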

How the results depend on the processing

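All alternatives here were planned. Array weights raised the count of genes from 29 to 54, with 37 higher and 17 lower, and every probe set as its own feature gave 45 features, 36 of them higher. Without dim genes 5 were lower instead of 9, because 21 of the 29 genes were then tested. Leaving out an array gave 5 to 47 genes, 4 to 32 higher and 1 to 15 lower; fewer arrays are part of that, but the rise without Ly-6C-negative replicate 2, the array with the highest first component score, is not, and its cause was not tested. The lists past the threshold numbered 3 with an estimated correlation and 4 with fry instead of 9. For the array weights the cause was not tested. The estimated correlations of the early T cell receptor, Ly6 family, TGF-beta and thymocyte lists were 0.0053, 0.0034, -0.0085 and -0.0088. These lie below the preset 0.01, yet the adjusted p rose, so a higher correlation is not the cause for these lists. Other lists that passed had higher ones, up to 0.0670 for the cytokine receptor list. The lower list counts were not tested further. All other counts of genes lay within 1.5 times of 29: 29 after a second quantile normalization, 34 with array medians subtracted, 20 without dim genes, 29 with mean probe sets, 27 with trend and robust settings, 41 with the replicate block, 40 at an adjusted p of 0.1, 23 with a 1.5-fold minimum, 29 without the Ly6 family and 21 without Ly-6C-negative replicate 3. The 29 genes kept their direction under every alternative that tested them. Leaving out or weighting arrays could not have changed it, because their groups do not overlap. The replicate block and the trend and robust settings leave the difference itself as it is. Among single named genes over all alternatives, 80 values lost a call, most of them with an array left out, and 12 gained one, and among lists 28 lost and 8 gained one; none that had passed changed direction, while 16 gene values and 51 list values that had not passed changed sign. The regulatory T cell, early T cell receptor and inhibitory lists passed under every alternative, with adjusted p up to 0.0423, 0.0375 and 0.0423. Among named genes and lists the replicate block changed no other call than those given with it. The table gives no detection calls, so dim genes cannot be told from background; the median gene lay at 6.37, above the levels of most NK markers.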

Other observations

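The tests of cell shares in this part were chosen after the results were seen; the list tests and the regroupings of arrays were planned. Interferon response genes did not pass the test as groups. The type I interferon list had a median difference of 0.0070 over 45 members (camera adjusted p = 0.664), with no member past the threshold over all genes or adjusted over the list alone, Oasl2 at -0.31, Mx2 at 0.34 and Stat2 at 0.19. The interferon gamma list had a median difference of -0.060 over 22 members (camera adjusted p = 0.154); 0 passed over all genes and 1, the GTPase gene Iigp1 at -0.33, adjusted over the list alone; without dim genes the list passed (camera adjusted p = 0.0159), in a range over the alternatives up to 0.946. MHC class I genes had a median difference of -0.059 over 16 members (camera adjusted p = 0.558), with Psmb9, an immunoproteasome gene, at -0.16 and no member past either threshold. The T cell receptor signalling machinery had a median difference of 0.010 over 36 members (camera adjusted p = 0.923), with 1 lower adjusted over the list alone, Sit1 at -0.39, and Rasgrp1 at 0.22 and Txk at -0.23.

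Genes of quiescence, movement and metabolism did not pass as lists either, and in the main fit none of their members passed over all genes; among named genes, Tnfrsf1b of the NF-kB list passed with the replicate block and Dapl1 of the naive and quiescence list without Ly-6C-negative replicate 2. Naive and quiescence genes had a median difference of 0.019 over 37 members (camera adjusted p = 0.214), with Bcl2 at 0.21 and Bach2 at 0.16; the list passed without Ly-6C-negative replicate 2 (camera adjusted p = 0.0227), in a range up to 0.898. Ccr7, a receptor for lymph node homing, differed by 0.017 and Il7r, the IL-7 receptor gene, by -0.042. Migration and adhesion genes had 0.017 over 37 members (camera adjusted p = 0.670), NF-kB genes 0.028 over 26 members (camera adjusted p = 0.399), and glycolysis and transport genes 0.044 over 24 members (camera adjusted p = 0.409), with Aldoa at -0.23; this list passed without Ly-6C-negative replicate 2 (camera adjusted p = 0.0274), in a range up to 0.862. Cholesterol synthesis genes had 0.041 over 24 members (camera adjusted p = 0.133), with 1 member, Cyp51 at 0.43, past the threshold adjusted over the list alone and Hmgcs1 at 0.26; the list passed without Ly-6C-negative replicate 2 (camera adjusted p = 0.0209) or Ly-6C-positive replicate 2 (0.0498), with array weights (0.0495) and over every probe set (0.0345), in a range up to 0.617. Apoptosis regulators had -0.0019 over 18 members (camera adjusted p = 0.949), dissociation and stress genes 0.0050 over 28 members (camera adjusted p = 0.949), with Jun at -0.30, and T cell receptor segments, whose sequences overlap, -0.032 over 8 members (camera adjusted p = 0.399), with Trav19 at -0.24 past the threshold adjusted over the list alone.

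The 6 arrays can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real grouping, 1 of the 10, gave 29 genes, and the highest of the others 0. For the lists, 1 of the 10 gave as many as the real 9, the real one itself, and the highest of the others gave 7, among them 4 of the real 9. That grouping, which exchanges the replicate 2 arrays, is 1 of the 4 that part all 3 pairs. Its smallest adjusted p was 0.00858, for the early T cell receptor list among others, and the lowest adjusted p of the regulatory T cell list in any other grouping was 0.00681, against 2.05e-16 in the real one. The effector and memory list and the cytokine receptor list reached a lower adjusted p in another grouping, 0.00721 and 0.0272, than in the real one, 0.00827 and 0.0438. At an unadjusted p under 0.05 the real grouping had 1337 genes and another had 1339.

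Regulatory T cell signature genes were higher in Ly-6C-negative cells, with a median difference of 0.16, and both sorts were gated on CD44-low, CD25-negative and Foxp3-negative cells. A larger share of CD44-high memory cells in the Ly-6C-negative sort would raise Cd44. The upper 95% bound of its difference was -0.105, which argues against this as the source as far as Cd44 alone can tell. Cd44 did not pass over all genes (limma adjusted p = 0.427). The effector and memory list was higher (camera adjusted p = 0.00827, and 0.531 with an estimated correlation). Adjusted over that list alone, 8 members were higher and 4 lower, so a small share is not excluded. A larger share of Foxp3+ regulatory T cells would raise Foxp3 and Tnfrsf18, which differed by 0.013 and -0.012. The highest of their upper 95% bounds was 0.260, for Tnfrsf18. It lies below the lowest lower bound of the 6 members higher over all genes, 0.339 for Tnfrsf9. That order was set by the choice of members, since passing the threshold takes a lower bound well above no difference. The lowest among all 20 higher genes, 0.285 for Zfp101, also lies above 0.260. Foxp3, at 6.67, moreover lies close to the median gene at 6.37. These bounds therefore cannot decide whether such a share is the source of those 6, although neither Foxp3 nor Tnfrsf18 showed a rise. Il2ra lies below the median gene, and its upper bound was 0.398. That lies above the lower bounds of Tnfrsf9 and Gpr83, 0.339 and 0.385, and below the lowest of the others, 0.449 for Ikzf2. For the 12 members higher only when adjusted over the list alone, taken as a set, the explanation cannot be told apart. Their lowest lower bound, 0.0327 for Igf1r, lies below 0.260, although that of Icos, 0.370, lies above 0.260 and below 0.398. The list does not separate genes that regulatory T cells raise from genes that they lower, so the bound of a single member such as Igf1r does not decide. A difference among Foxp3-negative naive cells themselves may also account for the pattern and was not tested further.

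The thymocyte and recent thymic emigrant list was higher in Ly-6C-negative cells, although Dntt and Slc16a5, which belong to it, were lower. More recent thymic emigrants in the Ly-6C-negative sort may be a part of the shift: Rag1, Rag2, Ccr9 and Plxnd1 had a median difference of 0.0710. This does not decide, since the 4 genes belong to the list, and the explanation cannot be told apart because all 4 lie below the median gene at 6.37, the highest being Ccr9 at 6.07. Cd24a, also of the list, was higher past the threshold with the replicate block and not in the main fit, and was not part of this test. The lower Dntt and Slc16a5 were not explained by any test here.

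Klrd1, Gzma and Il18r1 are the members of the effector and memory list that passed and were lower, grouped only after their values were seen; the list as a whole was not lower. More CD8 T cells in the Ly-6C-positive sort, which gated out CD8+ cells, would lower Cd8b1 with them. Cd8a, at 6.27, lies below the median gene and was left out. Gzma, with group means of 5.42 and 6.11, lies below the median gene too and was kept among the 3 genes. Cd8b1 differed by 0.16, -0.051 and -0.47 in the 3 pairs, against medians of -0.64, -0.85 and -0.71 for the 3 genes. Its lower 95% bound of -0.403 lies above their highest upper bound of -0.457. The 3 genes were picked for having passed, which by itself sets their bounds apart from no difference. This therefore argues only weakly against more CD8 T cells as the whole source. More NK cells in the Ly-6C-positive sort, which gated on TCRβ, remain possible: 7 NK markers had a median difference of -0.0121, but 5 of them lie below the median gene, and of the other 2, Tyrobp and Il2rb, Il2rb was higher in Ly-6C-negative cells by 1.12. The explanation cannot be told apart from a difference within the CD4 T cells because most of these markers lie below the median gene.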
